A study of Mus musculus with 18 samples.

How the data were processed

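Liver RNA was measured by RNA sequencing in 18 mouse libraries, from NRF2 WT and KO animals at 2 days (2D), 4 weeks (4W) and 36 weeks (36W) after diethylnitrosamine, with 3 libraries in each of 6 groups. The labels give a mixed B6;129P2 strain, RNA from flash-frozen material, and TruSeq libraries from total RNA. The authors deposited raw read counts per gene, 1 column per library, with no normalisation applied: the values are whole numbers, and total counts differ between libraries. The deposited table also holds other columns, with the start, end and length of each gene. The tools STAR 2.5, HTSeq and DESeq2 and the genome build mm10 are named in the submitters' processing notes, without their roles, settings or annotation release, and the strand of the libraries is not stated, so that reads from overlapping genes on the other strand can be included in a count.

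The table had 35275 genes, of which 11853 had no count in any library. Of the gene identifiers, 34490 were found in the GENCODE M21 annotation of mm10 and 79.4% of these had the same start there. Gene names were taken from the table, except for 27 names turned into dates by a spreadsheet. These were replaced by the reference name of their gene identifier, or by the identifier where no name was found. Totals ranged from 15.3 to 24.2 M counts. A floor of 3 counts, which is 0.124 to 0.196 CPM depending on the library, was used as the level a count of 0 allows. Floors cover counting error only. The labels do not say that each library comes from a separate animal, so p-values measure the spread between samples. An exact permutation of 3 against 3 libraries cannot give a p below 0.1, and tests that pool information across genes were used instead.

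KO was compared with WT at each time in a fit of the 6 libraries of that time alone, with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, genes kept by filterByExpr) and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The differences of the KO effect between times, and the comparisons of times within a genotype, used one edgeR fit of all 18 libraries with 6 group means. Calls at the 3 times were intersected and the shared counts compared with the product of the shares and with Fisher's exact test. Genes within 10 Mb of Nfe2l2 were compared with the rest of the genome by Fisher's exact test. The genes, 44 gene lists, tests and alternatives were fixed before the data were examined, except where the text says that a choice came later. For each list the number of called members was counted, over all genes and adjusted over the list alone, and lists with at least 3 tested members were tested with camera from limma 3.58.1 (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists of a comparison. Under an estimated correlation 0 lists were called in the KO against WT comparisons, where camera called 12, 20 and 22 at 2D, 4W and 36W and fry called 0, 1 and 0. The result of each list is given for 4W, and for the other comparisons that of a part of the lists.

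The named genes were set by a rule. Nfe2l2 came first. Next came the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those called, with an average log2 CPM of at least 1, no overlap between the KO and WT libraries, and no predicted or clone-type name. Groups of 3 do not overlap for 10% of genes by chance. For each list up to 4 called members with the smallest p-values followed, or the member with the smallest p-value where none was called. Differences and time comparisons used the 5 largest in each direction and up to 2 called members per list. Some genes that met the rule are not reported here. The genes given for the comparison without the third WT library of 2D, and the markers used to describe single libraries, were chosen after their values were seen.

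The pipeline was tested on simulated data that had the means and spread of the real tables, with 100 genes changed 2-fold and 100 changed 4-fold among those averaging at least 20 counts. At 2D, 4W and 36W it recovered 44, 68 and 14 of the genes changed 2-fold and 83, 93 and 85 of those changed 4-fold, in the right direction. Of its calls 8.63%, 9.55% and 7.48% were unchanged genes, above the 5% aimed at. The difference tests recovered 21 (2D minus 4W), 17 (36W minus 4W) and 26 (36W minus 2D) of the genes changed 2-fold and 66, 77 and 74 of those changed 4-fold. The time comparisons recovered between 46 and 61 of the genes changed 2-fold and between 81 and 89 of those changed 4-fold. Each gene was simulated independently and no simulated library stood apart from its group, so recovery in the real libraries can be lower.

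Alternatives were DESeq2 1.42.0 with its defaults, limma-voom, DESeq2 size factors or library size alone as the scaling in edgeR, no low-count filter, a filter of CPM of 1 or more in 3 samples, replicate number as a block, the fit of all 18 libraries, a minimum of a 2-fold change, windows of 5 and 20 Mb, and leaving out each library in turn. After the data were seen, a fit of 17 libraries without the third WT library of 2D and a fit of the 12 libraries of 4W and 36W were added. Correlations of the same replicate number across genotypes and a count of differences between libraries were used to check for pairing and duplicated libraries. Alternatives planned for values that are not counts did not apply. The work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.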

Results

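The study profiled liver RNA from mice with a working NRF2 gene (WT) and from NRF2 knockout mice (KO) after diethylnitrosamine (DEN), a carcinogen that forms DNA adducts in hepatocytes. NRF2, encoded by Nfe2l2, is the transcription factor that drives antioxidant and detoxification genes. There were 18 RNA sequencing libraries in 6 groups of 3, WT and KO at 2 days (2D), 4 weeks (4W) and 36 weeks (36W) after DEN. The labels call the 2D material liver tumor and the 4W and 36W material liver tissue, while the extraction text, shared by all samples, speaks of removed tumours, so the share of tumour in a library is not known. The 2D material was taken only 2 days after DEN, and its label is not used here as evidence of tumour. Gene counts summed to between 15.3 and 24.2 M per library, with a median of 18.5 M. A count of 3 reads, taken as the floor of detection, equals 0.124 to 0.196 CPM (counts scaled to 1e6 per library), and 12908 to 14660 genes had 10 counts or more in a library. Values below are TMM-scaled CPM, mean ± SD with n = 3, or log2 fold changes of KO over WT with their standard error (SE). A gene is named as called when its adjusted p from edgeR's quasi-likelihood test was under 0.05.

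Nfe2l2 itself (chromosome 2, 75675513 to 75704641, mm10) was the first gene examined. At 2D the 3 WT libraries had 73.1, 70.2 and 76.1 CPM and the 3 KO libraries 43.2, 66.3 and 67.8 CPM, a log2 fold change of -0.32 (SE 0.17, adjusted p = 0.396). At 4W the WT libraries had 109, 109 and 90.0 CPM and the KO libraries 54.0, 55.1 and 56.2 CPM, so that Nfe2l2 fell by 0.90 on the log2 scale (adjusted p = 0.00211). At 36W the WT libraries had 110, 127 and 105 CPM against 42.9, 37.7 and 43.0 CPM in KO, and Nfe2l2 fell by 1.44 (adjusted p = 0.0328). The fold at 36W was lower than that at 2D by a log2 difference of -1.16 (adjusted p = 0.0109). A count per gene cannot show which part of the transcript remains in KO, so these levels do not measure loss of the protein. Nqo1, a quinone reductase and classical NRF2 target, separated the genotypes in every library. It ranged from 14.2 to 29.1 CPM in WT and 1.37 to 2.27 CPM in KO at 2D, from 11.2 to 17.5 against 2.11 to 4.17 CPM at 4W, and from 22.6 to 103 against 0.752 to 6.40 CPM at 36W. Within 10 Mb on either side of Nfe2l2, where DNA from the donor strain can persist around an engineered gene, 3 of 93 tested genes were called at 4W (Nfe2l2, Itga4 and Tlk1; 3.23% against 6.10% elsewhere, Fisher's exact p = 0.379, two-sided). At 36W the single called gene of 92 there was Nfe2l2 (Fisher's exact p = 0.0336 with it, p = 1 without it). At 2D edgeR called 0 of 96, against 1 in the fit of all 18 libraries.

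**Figure D1:**
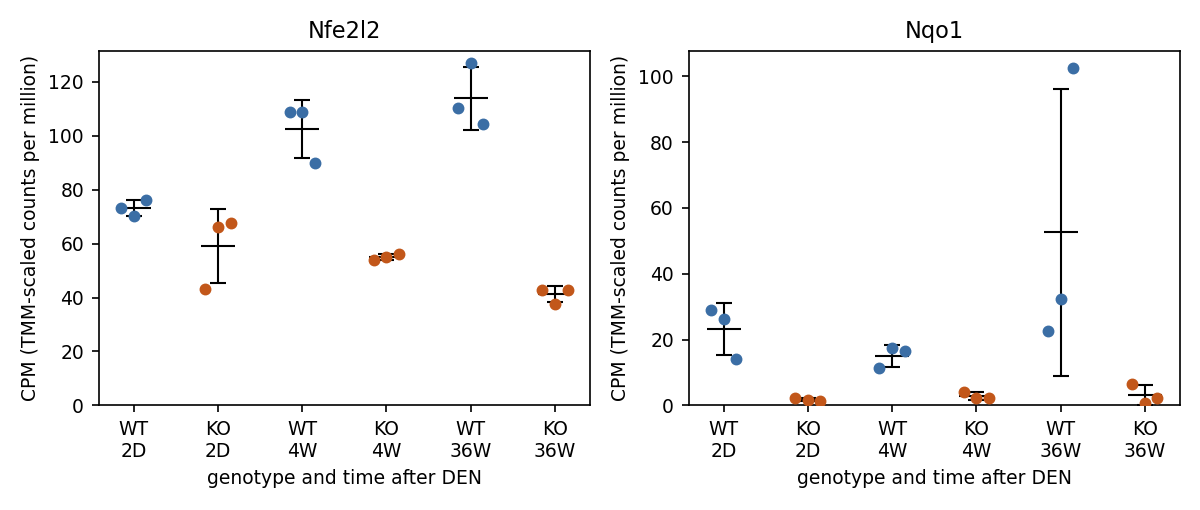
Nfe2l2 and Nqo1 in TMM-scaled CPM (linear y axis) in the 6 groups on the x axis; points are libraries, the dash is the mean and the bars show 1 SD (n = 3). Nqo1 lay at 6.40 CPM or lower in the KO libraries and at 11.2 CPM or higher in the WT libraries, while Nfe2l2 reached 67.8 CPM in KO at 2D.

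The comparison of KO with WT at 2D shows how the genotypes differed 2 days after DEN. No group without DEN was sampled at any time. A changed response to DEN therefore cannot be told apart from a difference between the genotypes that was there before it. Several detoxification genes were lower in KO. The glutathione transferase Gsta1 stood at 4.43 ± 1.65 CPM in WT and 0.103 ± 0.0526 CPM in KO (log2 fold change -5.37, SE 0.54, adjusted p = 0.0233). That KO level lies under the floor of 3 counts, so the size of the fold is uncertain. Gstm1, another glutathione transferase, fell from 451 ± 48.2 to 63.1 ± 9.53 CPM (-2.85, adjusted p = 0.00172). Nqo1 fell by 3.76 on the log2 scale (adjusted p = 0.0227) and Ces1g, a carboxylesterase, by 3.48 (adjusted p = 0.000589). Slc15a2, a peptide transporter, had a log2 fold change of -3.85 (adjusted p = 0.0321), Cbr3, a carbonyl reductase, one of -2.51 (adjusted p = 0.049), and Gstm3, Pir, Cyp2c50 and Gstm2 ones of -2.24, -2.16, -2.01 and -1.99. In the other direction, the activin subunit gene Inhbe rose from 7.94 ± 1.83 to 31.02 ± 8.45 CPM (1.94, adjusted p = 0.049). Ide, which encodes an insulin-degrading protease, rose from 48.0 ± 3.61 to 132 ± 4.60 CPM (1.44, adjusted p = 0.00417). The glutamate transporter Slc17a8 rose by 1.32, Vwa8, a mitochondrial ATPase, by 0.81 and Msrb1, a methionine sulfoxide reductase, by 0.75 on the log2 scale (adjusted p = 0.0321, 0.049 and 0.049). Reads of the closely related Gsta1 and Gsta2, of the Gstm family and of the Ces1 family can be assigned to the wrong member, so the value of a single member is less certain than that of the family.

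Among the gene lists at 2D, 8 of the 44 tested NRF2 targets were lower and none of these 44 was higher, and adjusted over the list alone 25 were lower (median log2 fold change -0.64, camera adjusted p = 3.3e-42; adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone, 12 of 21 acute phase genes were higher, a set of plasma proteins made by the liver in inflammation (median 0.66, camera adjusted p = 1.32e-12; adjusted p = 0.68 with an estimated correlation). Itih4, its member with the smallest p-value, measured 2504 ± 238 CPM in WT and 4291 ± 426 CPM in KO, with an adjusted p over all genes of 0.0913. Of 27 fatty acid oxidation and PPAR alpha target genes, 12 were higher when adjusted over the list alone (median 0.35, camera adjusted p = 5.25e-09; adjusted p = 0.68 with an estimated correlation). The fatty acid binding protein gene Fabp1 led them with 156 ± 45.3 CPM in WT and 378 ± 52.0 CPM in KO (1.26, adjusted p = 0.0756). B and plasma cell genes had a median of 0.99 (camera adjusted p = 7.09e-07; adjusted p = 0.638 with an estimated correlation), with 4 of 10 higher over the list alone. Sinusoidal endothelial genes had a median of -0.40 (camera adjusted p = 1.78e-05; adjusted p = 0.68 with an estimated correlation), with 2 of 16 lower over the list alone. In all, edgeR called 23 of 13913 genes, 6 higher and 17 lower, while 2236 genes had an unadjusted p under 0.05 where 696 would by chance. With library size as the only scaling, which shifts the median gene by -0.10 on the log2 scale, 29 genes were called, 2 higher and 27 lower. The balance turned with DESeq2, which called 425 higher and 327 lower, and in the fit of all 18 libraries, which called 65 higher and 36 lower. The fit of all 18 libraries kept 11 of the 23 calls. Gsta1, Slc15a2, Cbr3, Gstm3, Cyp2c50, Gstm2, Slc17a8 and Vwa8 were not called in it.

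The third WT library of 2D stood apart. Its collagen transcripts Col1a1 and Col3a1 measured 1190 and 2476 CPM, against 64.8 to 164 and 234 to 513 CPM in the other 5 libraries, and the bile duct keratin Krt19 measured 65.7 CPM against 1.11 to 5.30 CPM. The spread of its genes around the group mean had an SD of 0.379 (log2), where the other 5 libraries had 0.154 to 0.232. Without that library, a choice made after its values were seen, edgeR called 1853 of 14147 genes at 2D, 945 higher and 908 lower, and all 23 genes called with it were kept. In that smaller comparison 28 of 45 NRF2 targets were lower (Nqo1 -4.01, Srxn1 -2.04), 10 of 21 acute phase genes were higher (Orm2 4.37, Saa2 3.74), and 8 of 24 interferon response genes were higher with 1 lower (camera adjusted p = 9.1e-40, 0.000137 and 0.000198; adjusted p = 0.566, 0.765 and 0.765 with an estimated correlation). The chemokine Cxcl1 rose by 3.82, the muscle-type carbonic anhydrase Car3 by 4.02 and the cyclin Ccnd1 by 2.27, and the aminotransferase Tat and the asparagine synthetase Asns fell by 2.17 and 2.18. Fatty acid oxidation genes had 7 higher and 2 lower of 27, and fatty acid synthesis genes 7 higher and 2 lower of 17. Over the list alone, 9 of 11 B and plasma cell genes were higher and 5 of 16 sinusoidal endothelial genes were lower. Leaving out 1 of the other libraries gave 2 genes (WT replicate 1), 5 (WT replicate 2), 2 (KO replicate 1), 1 (KO replicate 2) and 2 (KO replicate 3).

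At 4W, a time after the acute injury, KO livers differed from WT in detoxification, protein folding, interferon and lipid genes together. Gsta1 fell from 15.8 ± 3.22 to 0.172 ± 0.298 CPM (log2 fold change -6.46, SE 0.67, adjusted p = 0.00148), a size that is uncertain because 2 KO libraries had a count of 0. Tsku, a secreted hepatokine, fell from 112 ± 52.3 to 2.96 ± 0.548 CPM (-5.25, adjusted p = 0.000342). The carboxylesterases Ces2c and Ces1b fell by 4.16 and 3.76 on the log2 scale (both adjusted p = 3.93e-05). Cyp2a5, a coumarin hydroxylase, fell from 565 ± 146 to 36.9 ± 14.5 CPM (-3.95, adjusted p = 0.000281). Thrsp, a lipogenic factor, fell from 466 ± 235 to 51.3 ± 27.1 CPM (-3.19, adjusted p = 0.00631). Gsta2, Cbr3, Fitm1 and Gstp2 had log2 fold changes of -3.41, -3.13, -3.12 and -3.11. The insulin-like growth factor binding protein gene Igfbp1 rose from 30.6 ± 23.1 to 323 ± 127 CPM (3.39, adjusted p = 0.00582), the metallothionein Mt1 from 46.5 ± 8.66 to 268 ± 158 CPM (2.52, adjusted p = 0.00488). Pdk4, which restrains glucose oxidation, rose from 9.98 ± 2.41 to 52.6 ± 32.5 CPM (2.39, adjusted p = 0.0157). S100a9, Corin, Nr4a1, Mt2, Il1rn, Cyfip2 and Med12l rose by 2.66, 2.48, 2.43, 2.31, 2.19, 2.15 and 2.13. Igfbp1, Pdk4 and Thrsp respond to fasting, and a different feeding state of the KO animals stays open for them.

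NRF2 targets were lower in 31 of 44 tested genes at 4W, and in 36 adjusted over the list alone (median -0.90, camera adjusted p = 2.51e-65; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 0.00881). Among them the glucuronosyltransferase Ugt2b35 fell by 2.21, Gstm1 by 2.91, the aldehyde oxidase Aox1 by 2.54 and Gstm4 by 1.76. Of 18 genes of the unfolded protein and integrated stress response, 11 were lower, 13 over the list alone, while 1 was higher over the list alone (median -0.93, camera adjusted p = 7.18e-20; adjusted p = 0.304 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 fell from 1599.9 ± 394 to 486 ± 40.5 CPM (-1.73, adjusted p = 0.00127), and Hyou1, Manf and Creld2 fell by 2.30, 2.38 and 2.80. Some cytosolic heat shock genes were lower too. Hspa1b fell from 51.7 ± 9.78 to 10.98 ± 0.824 CPM (-2.24, adjusted p = 0.000187). Hsph1, Hspa8 and Hsp90aa1 fell by 2.08, 1.19 and 1.26, so that 5 of the 15 immediate early and heat shock genes were lower and 1 was higher (camera adjusted p = 2.01e-06; adjusted p = 0.508 with an estimated correlation). Interferon response genes were lower in 12 of 24, and in 17 over the list alone (median -0.84, camera adjusted p = 1.11e-12; adjusted p = 0.508 with an estimated correlation), with Irf7 at -1.04, Isg15 at -1.72, Oasl1 at -1.21 and Lgals3bp at -0.60.

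Lipid and sugar genes at 4W went several ways. Of 30 fasting-responsive genes, listed after the 4W calls were seen, 25 differed in the direction of fasting. Among these were Fasn, Cyp4a14, Cyp4a10, G6pc, Ppargc1a and Me1, while Lpin1 was called against it. A different feeding state of the KO animals stays open for such genes. Cholesterol synthesis genes were lower in 10 of 22, 15 over the list alone (median -0.56, camera adjusted p = 5.63e-12; adjusted p = 0.508 with an estimated correlation), among them the squalene epoxidase Sqle (-1.12) and Mvd (-1.58). Fatty acid synthesis genes were lower in 3 of 17, namely Lpin1 (-1.73), Thrsp and the fatty acid synthase Fasn (-1.18; camera adjusted p = 0.0174; adjusted p = 0.672 with an estimated correlation). Of 27 fatty acid oxidation and PPAR alpha target genes, 5 were higher, 9 over the list alone (median 0.27, camera adjusted p = 2.01e-06; adjusted p = 0.672 with an estimated correlation). The fatty acid hydroxylase Cyp4a14 rose from 627 ± 127 to 2259 ± 558 CPM (1.84, adjusted p = 0.00201) and Cyp4a10, Acot2 and Ehhadh rose by 1.34, 1.83 and 0.98. The gluconeogenic gene G6pc rose by 1.98 and Ppargc1a by 1.04, Tdo2 fell by 0.79, and the list split into 4 higher and 2 lower of 18. Aldoa fell by 0.42, and 2 of 20 glycolysis genes were lower (camera adjusted p = 0.0483; adjusted p = 0.672 with an estimated correlation). In the pentose phosphate and NADPH list Tkt, Pgd and Me1 fell by 0.65, 0.59 and 1.28, 3 of 11 (camera adjusted p = 0.0174; adjusted p = 0.672 with an estimated correlation). Drug-metabolising cytochromes had 4 lower and 1 higher of 23 (Cyp1a2 -0.80, Cyp3a11 0.77; camera adjusted p = 0.0204; adjusted p = 0.672 with an estimated correlation).

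Immune and cell type lists at 4W showed smaller counts. The antigen presentation genes H2-Eb1, H2-Ab1, Cd74 and H2-Aa rose by 1.04, 1.06, 1.04 and 0.96, the 4 higher against 1 lower of 19 macrophage and Kupffer cell genes (camera adjusted p = 0.0242; adjusted p = 0.698 with an estimated correlation). Acute phase genes had 3 higher and 1 lower of 22 (Itih4 0.88, Hp 0.72, Hamp -1.36; camera adjusted p = 0.0242; adjusted p = 0.698 with an estimated correlation). S100a9 and S100a8, the 2 called of 3 tested neutrophil genes, stood at 3.51 ± 2.16 and 1.32 ± 0.608 CPM in KO (camera adjusted p = 0.00999; adjusted p = 0.672 with an estimated correlation). Sinusoidal endothelial genes had 2 higher of 16 (Fcgr2b 0.76, Kdr 0.59; camera adjusted p = 0.0174; adjusted p = 0.674 with an estimated correlation), cholangiocyte genes 1 of 11 (0.0242 and 0.672 on the same tests), and male-biased liver genes 2 lower of 14 (Cyp7b1 -1.87, Hsd3b5 -2.04; 0.00999 and 0.672). Among the libraries, KO replicate 2 had the highest macrophage score of 4W (0.75 against -0.26 to -0.05) and KO replicate 3 the highest Col1a1 (277 CPM against 30.7 to 85.2). The oncogene Myc fell by 1.90, the 1 lower of 29 oncogenic signalling genes (camera adjusted p = 0.973). Rrm2, a ribonucleotide reductase subunit, fell from 18.9 to 6.26 CPM, the 1 lower of 35 cell cycle genes, whose median was -0.65 (camera adjusted p = 0.000813; adjusted p = 0.672 with an estimated correlation).

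Other lists at 4W are given by their called members. Ftl1, Hfe and Hamp fell by 0.90, 0.60 and 1.36 among 17 ferroptosis and iron genes (camera adjusted p = 0.0174; adjusted p = 0.508 with an estimated correlation). Ftl1 is on the NRF2 target list too. Aldh1l1 and Shmt2 fell by 0.60 and 0.51 among 21 serine, one-carbon and purine genes (camera adjusted p = 0.0855). Cth and Bhmt of the methionine cycle fell by 0.50 and 0.83 (2 of 17, camera adjusted p = 0.127), Cyp7b1 and Cyp27a1 of bile acid synthesis by 1.87 and 0.63 (2 of 16, 0.102), and the clock genes Per2 and Bhlhe41 by 1.39 and 3.65 (2 of 17, 0.198). Pericentral hepatocyte genes had 4 lower of 17 (Rhbg -1.48, Glul -0.78; camera adjusted p = 0.114), periportal genes 2 higher and 3 lower of 15 (Hsd17b13 0.56, Mfsd2a -2.25; 0.707), and general hepatocyte genes 4 lower of 20 (Foxa2 -1.21, Hnf4a -0.58; 0.484). The p53 list split between Gdf15, which rose by 1.48, and Cdkn1a, which fell by 0.92 (camera adjusted p = 0.365), and the tumour and fetal marker list between Tff3 (1.94) and Ly6d (-1.82; 0.294). Kat2b of the epigenetic regulators rose by 0.49 (1 of 45, camera adjusted p = 0.0627), Nfkbia of the cytokine list by 0.63 (1 of 14, 0.102), and Psmb5 of the proteasome fell by 0.51 (1 of 22, 0.154). Besides Nfe2l2, the other 9 genes of the NRF2 pathway core list were not called (camera adjusted p = 0.112). The list medians were -0.04 for DNA repair, 0.47 for female-biased genes, 0.08 for sex chromosome genes, 0.47 for T and NK cells, 0.88 for B and plasma cells (camera adjusted p = 0.0249; adjusted p = 0.672 with an estimated correlation), 0.51 for stellate cells, 0.10 for erythroid genes, 0.13 for mitochondrially encoded genes and -0.15 for nuclear oxidative phosphorylation (camera adjusted p = 0.0485; adjusted p = 0.698 with an estimated correlation). Of the lists for carry-over from pancreas and fat and from muscle, 1 gene each was measured (Cela1 0.31, adjusted p = 0.375, and Mylpf -1.11, adjusted p = 0.242).

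In total edgeR called 814 of 13394 genes at 4W, 261 higher and 553 lower, of which 100 and 187 changed at least 2-fold. The count rests in part on WT replicates 2 and 3, without which 360 and 380 genes were called. The fit of all 18 libraries, which shares one spread over all times, called 439 genes, and DESeq2 called 1297.

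**Figure D2:**
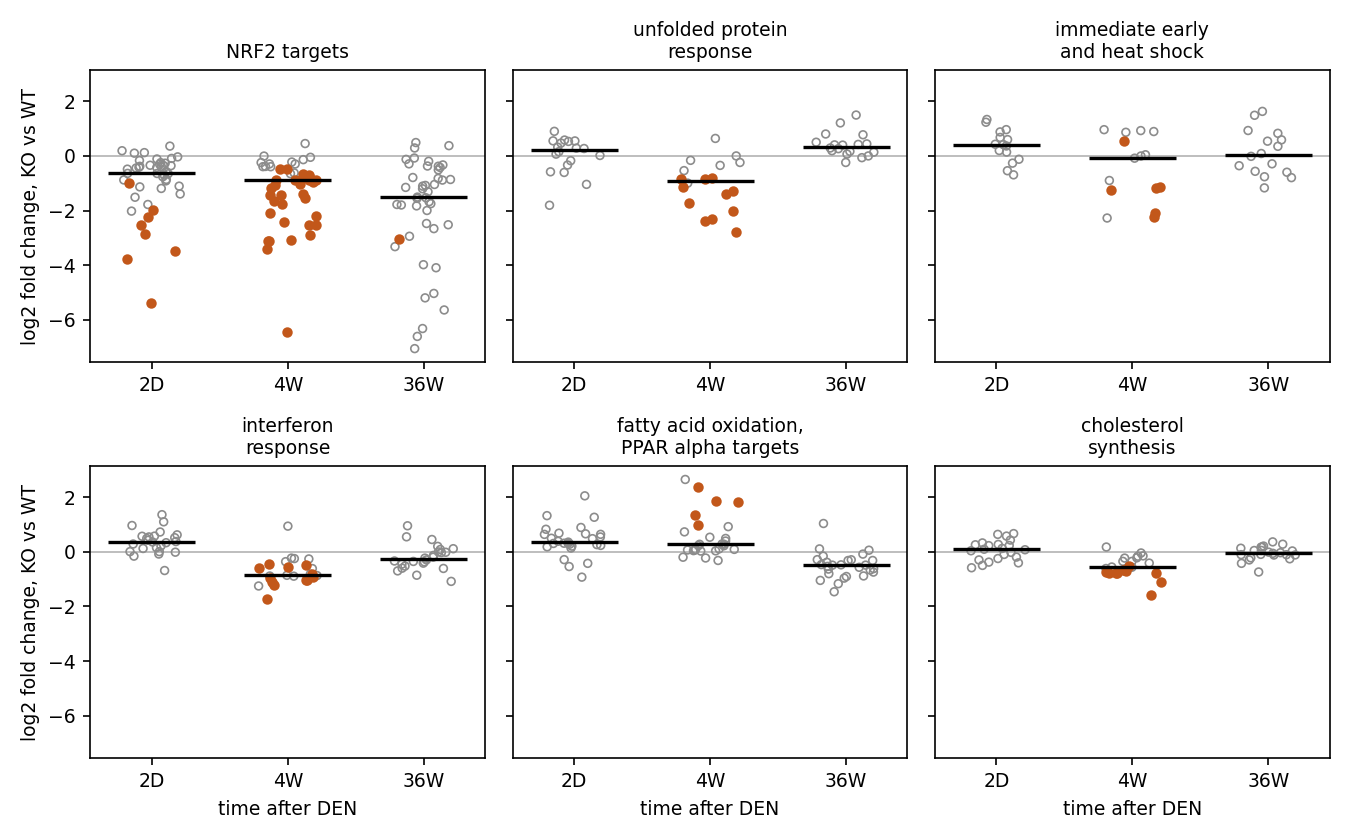
Log2 fold change of KO over WT (y axis, shared) for each tested gene of 6 lists at 2D, 4W and 36W (x axis); filled points are called genes, open points are not, and the line is the list's median. NRF2 targets had medians of -0.64, -0.90 and -1.51, and unfolded protein response genes medians of 0.21, -0.93 and 0.34 at the 3 times.

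At 36W, the latest time sampled, KO differed from WT in few genes at the threshold. The imprinted gene Peg3 rose from 4.22 ± 0.526 to 19.8 ± 2.10 CPM (log2 fold change 2.25, SE 0.18, adjusted p = 0.0328), Ace, the angiotensin-converting enzyme gene, to 14.9 ± 0.951 CPM (2.15, adjusted p = 0.0478). Id3, an inhibitor of differentiation factors, rose from 23.05 ± 1.40 to 69.6 ± 8.93 CPM (1.62, adjusted p = 0.0328). Ugt2b35 fell from 156 ± 55.8 to 18.4 ± 3.83 CPM (-3.06, adjusted p = 0.0328), and Nfe2l2 was the other lower gene. NRF2 targets had a median of -1.51 (camera adjusted p = 1.28e-44; adjusted p = 0.396 with an estimated correlation), and adjusted over the list alone 36 of 45 were lower, where 1 was lower over all genes and 29 were lower in the fit of all 18 libraries.

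In the fit of the 36W libraries alone, several lists passed only when adjusted over the list alone or as sets. Of their genes named below, Psrc1, Ppara and Hfe were called over all genes by edgeR in the fit of all 18 libraries (adjusted p = 0.0149, 0.0371 and 0.00206). Of 26 p53 targets, 11 were higher over the list alone (median 0.81, camera adjusted p = 8.49e-13; adjusted p = 0.399 with an estimated correlation), with Psrc1 at 8.54 ± 2.84 CPM in WT and 41.7 ± 24.9 CPM in KO (adjusted p over all genes 0.186). Fatty acid oxidation genes were lower in 7 of 27 over the list alone, and in 2 of 27 without WT replicate 1 (median -0.49, camera adjusted p = 1.68e-07; adjusted p = 0.399 with an estimated correlation), led by Ppara, the receptor that drives them, at 111 ± 12.9 CPM in WT and 52.8 ± 11.3 CPM in KO (adjusted p = 0.16). Macrophage and Kupffer cell genes were higher in 5 of 20 over the list alone (median 0.65, camera adjusted p = 4.29e-06; adjusted p = 0.399 with an estimated correlation). Cytokine and chemokine genes were higher in 4 of 18 over the list alone (median 0.66, camera adjusted p = 0.000162; adjusted p = 0.399 with an estimated correlation). Without WT replicate 1 neither of these lists kept a gene that was higher over the list alone, at medians of 0.42 for macrophages and 0.63 for cytokines. Ferroptosis and iron genes were lower in 4 of 17 over the list alone (camera adjusted p = 0.000118; adjusted p = 0.396 with an estimated correlation), with Hfe at -0.84 (adjusted p = 0.123). Without WT replicate 1 that list had 4 lower and 2 higher over the list alone. It shares Ftl1 with the NRF2 targets, so the lists are not separate findings. Unfolded protein response genes had a median of 0.34 (camera adjusted p = 0.000162; adjusted p = 0.483 with an estimated correlation), and of 0.11 without WT replicate 1. T and NK cell genes had a median of 1.31 (camera adjusted p = 1.65e-05; adjusted p = 0.399 with an estimated correlation). KO replicate 3 alone had a T and NK score of 1.90 where the other 5 libraries had -0.34 to 0.56.

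The WT libraries of 36W differed from each other more than the KO libraries did, with SDs around the group mean of 0.314 to 0.377 against 0.202 to 0.244 (log2). WT replicate 1 had 10911 CPM of Mup20, a male-biased urinary protein gene, where the other 5 libraries had 752 to 1277 CPM. Its tumour and fetal marker score was -0.40 where the other 5 had 0.65 to 1.32. In all, edgeR called 5 of 13516 genes, 3 higher and 2 lower, while 1617 had an unadjusted p under 0.05 where 676 would by chance. DESeq2 called 296 (100 higher and 196 lower) and the fit of all 18 libraries called 401 (71 higher and 330 lower). The fit of all 18 libraries kept 4 of the 5 genes, but not Ace (adjusted p = 0.0747 with edgeR). With library size as the only scaling 4 genes were called, 3 higher and 1 lower. Leaving out 1 library gave 36 genes (without WT replicate 2), 2 (WT replicate 3), 1 (KO replicate 1) and 0 (WT replicate 1, KO replicate 2 or KO replicate 3). The comparison without WT replicate 1, chosen after its values were seen, had 1332 genes with an unadjusted p under 0.05.

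**Figure D3:**
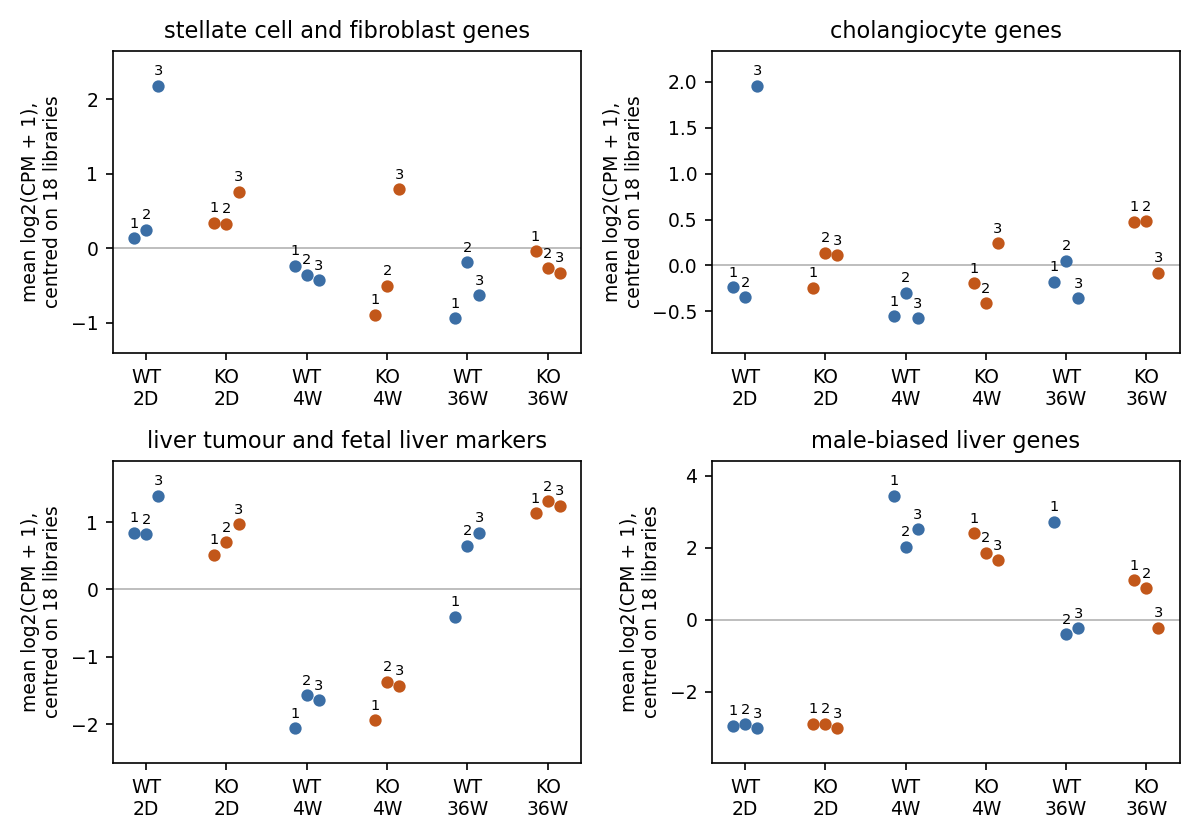
Mean log2(CPM + 1) of each list, centred on the 18 libraries (y axis), per library (numbered points) in the 6 groups (x axis). The third WT library of 2D had a stellate score of 2.18 and a cholangiocyte score of 1.96, and the first WT library of 36W a tumour and fetal marker score of -0.40.

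Whether the effect of the knockout differed between times was tested directly, as the difference of log2 fold changes in one fit of all 18 libraries. Higher and lower effects are meant by sign, so a lower effect can be a larger fall in KO. Between 2D and 4W, some unfolded protein response and heat shock genes had a higher effect at 2D. Creld2 and Hsph1 had an effect higher at 2D by 3.35 and 3.31, and Hyou1, Manf and Hsp90aa1 one higher by 2.77, 2.66 and 1.68. In counts, 7 of 18 unfolded protein response genes had a higher effect at 2D, 9 over the list alone (camera adjusted p = 3.94e-14; adjusted p = 0.205 with an estimated correlation; fry adjusted p = 0.0226), and 5 of 16 immediate early and heat shock genes (adjusted p = 0.276 with an estimated correlation). Interferon response genes had 1 such member of 24, Stat2 (1.23), and 12 over the list alone. Cholesterol synthesis genes had 2 of 22, among them Sqle (1.69), and 5 over the list alone (adjusted p = 0.276 and 0.58 with an estimated correlation). The effect at 2D was the lower one for Igfbp1 (-4.49), the lipoprotein receptor Vldlr (-2.73), Tat (-2.61) and Ppargc1a (-2.45). The test called 199 of 14877 genes, 150 higher and 49 lower, and 125 (79 and 46) with library size as the only scaling. Without 1 library the count was 531 (WT 2D replicate 3), 85 (WT 2D replicate 2), 106, 102 and 109 (KO 2D replicates 1, 2 and 3), 104 and 82 (WT 4W replicates 2 and 3), and 126 and 83 (KO 4W replicates 2 and 3).

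Between 36W and 4W, unfolded protein response genes differed as a list. The 4W libraries enter this difference and the one between 2D and 4W, so a low effect at 4W alone would show in both. The effect at 36W exceeded that at 4W for Creld2 (3.16), Manf (2.84), Hyou1 (2.27) and Ddit3 (2.31), which encodes the stress factor CHOP. Of 18 unfolded protein response genes, 6 differed, 13 over the list alone, and this list kept its call with each set test (camera adjusted p = 3.95e-24; adjusted p = 0.024 with an estimated correlation; fry adjusted p = 0.00176). The carboxylesterase Ces2c (3.36) and Id3 (2.75) also had a higher effect at 36W. The effect was lower at 36W for Ces1g (-4.55), the leptin receptor Lepr (-3.71), Vldlr (-3.15), Pdk4 (-2.99) and Ehhadh (-1.92), an enzyme of peroxisomal fatty acid oxidation. The latter 2 are the called members of 27 fatty acid oxidation genes, of which 13 differed over the list alone (adjusted p = 0.608 with an estimated correlation). The test called 84 genes, 42 in each direction, and 82 (68 and 14) with library size as the only scaling, which shifts the median by 0.12. Its one spread over all times can be too narrow for 36W. KO against WT at 36W went from 5 genes to 401 in the fit of all 18 libraries. A fit of the 12 libraries of 4W and 36W alone, chosen after the data were seen, called 9. Without 1 library the count was 22 and 9 (WT 4W replicates 2 and 3), 33, 53 and 9 (KO 4W replicates 1, 2 and 3), 53, 351 and 167 (WT 36W replicates 1, 2 and 3), and 232, 15 and 21 (KO 36W replicates 1, 2 and 3).

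Between 36W and 2D, some fatty acid oxidation genes and NRF2 targets had a lower log2 fold change of KO over WT at 36W. For Ugt2b35 that is a larger fall in KO, -3.06 at 36W against -0.65 at 2D in the fits of single times. Of 27 fatty acid oxidation genes 9 were lower, 17 over the list alone, among them Ppara (-1.75) and the dehydrogenase Acadm (-0.84). Of 45 NRF2 targets 5 were lower, 18 over the list alone, among them Ugt2b35 (-2.44) and Gclm (-1.44), a subunit of the enzyme that starts glutathione synthesis. The p53 list had 1 higher of 26, Sesn1 (0.94), and 11 over the list alone (adjusted p = 0.697 with an estimated correlation for each of these lists). Pericentral genes had 3 lower of 17 (Rnf43 -1.45, Slc13a3 -2.36; adjusted p = 0.697 with an estimated correlation). Ddit3 had the higher effect at 36W by 1.79, and Bex1, a tumour marker of the list, by 4.56. The test called 453 genes, 91 higher and 362 lower, but 237 (165 and 72) with library size as the only scaling, which shifts the median by 0.20 on the log2 scale. Without 1 library the count was 271, 105 and 757 (WT 2D replicates 1, 2 and 3), 217, 104 and 163 (KO 2D replicates 1, 2 and 3), 296 and 684 (WT 36W replicates 1 and 2), and 757, 197 and 120 (KO 36W replicates 1, 2 and 3).

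Some genes differed in the same direction at more than 1 time. Of 12803 genes tested at all times, edgeR called 12 in the same direction at 2 times, all lower. At 2D and 4W 10 genes were shared where 0.696 would be by chance (Fisher's exact p = 1.82e-10, two-sided), among them Ces1g, Gstm1, Nqo1 and Gsta1. The 2 shared at 4W and 36W were Ugt2b35 and Nfe2l2, the altered gene itself. The fit of all 18 libraries gave 51 such genes, 7 higher and 44 lower, of which Ces1g (-3.47, -2.52 and -7.07 at 2D, 4W and 36W), Gstm1 (-2.84, -2.90 and -4.00), Nqo1 (-3.74, -2.41 and -4.12), the ferritin light chain gene Ftl1 (-0.85, -0.89 and -1.13), the scramblase Plscr2 (-0.79, -0.95 and -0.75) and 1 clone-named gene were lower at all 3 times. DESeq2 gave 198, 83 higher and 115 lower, with 29 lower at all 3 times, among them Gsta1, Srxn1, Txnrd1 and Me1. With DESeq2, 68 higher genes were shared at 2D and 4W where 16.4 would be by chance (Fisher's exact p = 3.21e-24, two-sided). Across genes, which are not independent replicates, the log2 fold changes at 4W and 36W had a Pearson correlation of 0.25 and a Spearman correlation of 0.13. Those at 2D had Pearson and Spearman correlations of 0.01 and -0.02 with 4W, and of -0.02 and -0.14 with 36W.

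The livers also differed between times within each genotype, in comparisons where time after DEN, the age of the animals and any collection or library batch cannot be told apart, since the 2D titles carry another code than those of 4W and 36W. A different hour of collection cannot be told apart either, since clock genes differed. In WT, Arntl measured 19.7 to 31.8 CPM at 4W and 2.20 to 4.10 CPM at 36W, and Dbp 15.4 to 23.2 and 100 to 138 CPM. Per1 and Per3 were higher at 36W than at 4W in WT by 2.04 and 2.78. At 2D against 4W in WT, Per1 was higher by 3.00 and Nr1d1 lower by 2.28. The 36W and 2D comparisons share the 4W libraries. In WT at 36W against 4W, tumour and fetal liver markers were higher in 12 of 20, among them the desaturase Scd2, from 15.3 ± 4.36 to 474 ± 165 CPM (log2 fold change 4.95, adjusted p = 3.18e-06), and Golm1 (3.57), a Golgi protein used as a tumour marker. The serine synthesis genes Phgdh and Psat1 rose by 6.05 and 4.62 among 6 higher and 3 lower of 22. Cholesterol synthesis genes were higher in 14 of 22. Nuclear oxidative phosphorylation genes were lower in 22 of 23 (Cox5a -1.03, Ndufv1 -0.92) and mitochondrially encoded genes in 10 of 12 (mt-Atp6 -1.07). Pericentral genes were lower in 11 of 17 (Rhbg -2.17, Rgn -2.34), bile acid genes in 9 of 17 (Hsd3b7 -1.79) and methionine cycle genes in 12 of 17 (Cth -1.89). The drug-metabolising Cyp2b10 fell from 31.3 ± 14.6 to 0.109 ± 0.138 CPM. These lists had estimated-correlation adjusted p values of 0.257, and the serine list one of 0.594. The test called 3131 genes, 1772 higher and 1359 lower, against 1272 and 1743 with library size as the only scaling, which shifts the median by -0.10.

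In KO at 36W against 4W, the same tumour marker count, 12 of 20, was higher (Scd2 4.47, Ly6d 6.69). Unfolded protein response genes were higher in 15 of 18 (Ddit3 2.85, Manf 2.72; camera adjusted p = 9.53e-17; adjusted p = 0.109 with an estimated correlation), where WT had 3 of 18. Cholesterol synthesis genes were higher in 19 of 22. Fatty acid oxidation genes were lower in 23 of 27, with 1 higher (Ehhadh -3.08, Acadvl -1.58), bile acid genes in 14 of 17, and pericentral genes in 15 of 17 (Tbx3 -2.69). All 12 mitochondrially encoded genes were lower. Each of these lists had an adjusted p of 0.119 to 0.128 with an estimated correlation. Gadd45a and Psrc1, both p53 targets, rose by 2.55 and 3.41 among 11 higher and 3 lower of 26 (adjusted p = 0.668 with an estimated correlation). The test called 4436 genes, 2153 higher and 2283 lower.

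At 2D against 4W in WT, tumour and fetal liver markers were higher and cholesterol synthesis genes lower. Afp, the alpha-fetoprotein gene, stood at 4088 ± 2430.2 CPM at 2D and 4.90 ± 2.29 CPM at 4W (9.71, adjusted p = 1.04e-06), and Igf2 at 1469 ± 315 and 2.21 ± 1.43 CPM (9.36). Together 17 of 20 tumour and fetal markers were higher (adjusted p = 0.195 with an estimated correlation). The list mixes tumour with fetal liver markers, so its rise at 2D, here or in KO, cannot tell tumour from an immature liver. All 14 male-biased genes were lower, with the urinary protein gene Mup3 at 0.881 ± 0.521 CPM against 4420.0 ± 1373 CPM (adjusted p = 0.268 with an estimated correlation). In both genotypes the Y-linked gene Ddx3y measured 64.6 to 96.0 CPM at 2D and 67.6 to 75.1 CPM at 4W. Xist, the transcript of the inactive X chromosome, measured 0.217 CPM or less in these libraries, as in male animals. Cholesterol synthesis genes were lower in 21 of 22 (Fdps -4.72), a call kept with an estimated correlation (adjusted p = 0.0126). Fatty acid synthesis genes were lower in 14 of 17 (Scd1 -6.33) and interferon response genes in 22 of 24 (Stat2 -1.12; both adjusted p = 0.191 with an estimated correlation). Genes of the p53 list were higher in 19 of 26, with 1 lower (Tnfrsf10b 2.75, Zfp365 6.14; adjusted p = 0.35 with an estimated correlation), and cell cycle genes in 18 of 35 (Rrm2 1.64; adjusted p = 0.53). Stellate cell and fibroblast genes were higher in 13 of 19, with 1 lower (adjusted p = 0.604), a list raised in the third WT library of 2D. The test called 5606 genes, 2761 higher and 2845 lower, against 4817 and 1532 with library size as the only scaling, which shifts the median by 0.29.

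At 2D against 4W in KO, cholesterol synthesis genes were lower in 19 of 22 (Fdps -4.08, Insig1 -3.89), again with a call kept with an estimated correlation (adjusted p = 0.0154), and fatty acid synthesis genes in 12 of 17 (Scd1 -7.65; adjusted p = 0.202). All 14 male-biased genes were lower (adjusted p = 0.202). Cell cycle genes were higher in 28 of 35 (Rrm2 2.88, Mcm7 1.17; adjusted p = 0.234) and p53 genes in 18 of 26, with 2 lower (Cdkn1a 3.27; adjusted p = 0.368). Interferon response genes were lower in 11 of 24 (adjusted p = 0.529). Igf2 and Afp rose by 9.70 and 8.64 among 10 higher and 1 lower of 20 tumour and fetal markers (adjusted p = 0.202), all of these p values being with an estimated correlation. The test called 3605 genes, 1600 higher and 2005 lower, against 2727 and 1104 with library size as the only scaling, which shifts the median by 0.21. Without KO 2D replicate 3 and without KO 4W replicate 1 it called 2178 and 2268.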

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

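The tests of the libraries that stand apart and of the protein folding genes were chosen only after the results were seen. Each gene here had an effect of the knockout that differed between 2 times in the direct test. Higher and lower are again meant by sign. A higher effect can be a smaller fall in KO, as for Tsku (-1.94 at 2D and -5.25 at 4W in the fits of single times). Between 2D and 4W, Creld2, Selenbp2, Tsku, Hsph1 and Oas3 had an effect higher at 2D by 3.35, 3.33, 3.32, 3.31 and 3.04 on the log2 scale. Igfbp1, Zc3h6, Tff3, Nipal1 and Vldlr had differences of -4.49, -3.90, -3.19, -2.93 and -2.73. Between 36W and 4W, the differences were 3.36 for Ces2c, 3.16 for Creld2, 2.84 for Manf, 2.75 for Id3 and 2.31 for Ddit3, and -4.55 for Ces1g, -3.71 for Lepr, -3.15 for Vldlr, -2.99 for Pdk4 and -2.85 for the defensin Defb1. Between 36W and 2D, they were 4.76 for Gprc5a, 4.56 for Bex1, 4.42 for Mep1b and 4.22 for Ckmt1, and -3.98 for Ces1b, -3.81 for Ces1d, -3.56 for Fgf21, -3.50 for Cyp2j5 and -3.24 for Egln3. Col22a1, with 6.92, had a count of 0 in every WT library of 36W and 0.949 CPM in KO, so its size is not measured.

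Whether chance can be excluded was examined by regrouping the libraries. For the differences, WT and KO labels were exchanged within each time. That also breaks an effect of the knockout that is equal at both times. These counts therefore cannot exclude chance for a difference of effects. Between 2D and 4W, 1 of 100 groupings, the real one, called as many as 199 genes, and the highest other called 20. For 36W and 2D, 1 of 100 called as many as 453, and the highest other called 285. For 36W and 4W, 2 of 100 called as many as 84, and the highest other called 88. Within a single comparison only 10 groupings exist, which are too few. The real grouping, 1 of 10, called 23 genes at 2D, 814 at 4W and 5 at 36W, and the highest other called 0 each time. Without the third WT library of 2D the values were 1853 and 1. For the times in WT they were 3131 and 0 (36W against 4W) and 5606 and 1 (2D against 4W), and in KO 4436 and 0 and 3605 and 0.

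The third WT library of 2D had the highest value of the 6 libraries in 87.1% of the stellate and cholangiocyte genes, 27 of 31. That count does not test for more connective tissue and bile duct, since the library was singled out by the same lists, so the explanation stays open. A lower share of hepatocytes alone would raise the endothelial and macrophage scores of that library too. Set against the other WT libraries, these were -0.05 and -0.14, which argues against it as the only cause. The stellate score, from a list that singled the library out, exceeded the larger of them by 2.04 on the log2 scale. A KO animal under a WT label was excluded, since its NRF2 target score was 0.55 above the highest KO library.

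The lower unfolded protein and heat shock genes in KO at 4W were not explained by the scaling, under which the list's median stayed at -0.92 or lower. Nor were they explained by a lower share of hepatocytes, whose list had a median of 0.0317. A different feeding state or hour of collection of the KO animals stays open. Among clock genes at 4W, Dbp measured 15.42, 23.15 and 15.75 CPM in WT and 1.308, 18.05 and 2.696 CPM in KO. Per2 measured 20.04 to 34.35 CPM in WT and 6.884 to 12.2 CPM in KO. Per1, Nr1d1 and Arntl overlapped between the genotypes. KO replicate 2, with Dbp inside the WT range, had 452 CPM of Hspa5, against 531 and 475.7 CPM in the other KO libraries. The hour cannot be decided from 1 library. Of 30 fasting-responsive genes, 83.3% had a fold change in the direction of fasting, 11 of them called and 1 called against it, and that share was 33.3% at 2D and 56.7% at 36W. It does not test feeding, since the genes were listed after the 4W calls were seen and changes near 0 count, such as 0.03 for Fgf21. An effect of NRF2 on the unfolded protein and heat shock genes stays open too, since any difference in feeding between the groups would coincide with genotype.

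In the first WT library of 36W, 63.2% of the tumour and fetal markers, 12 of 19, were lowest of the 6 libraries and 68.2% of the pericentral, bile acid and male-biased genes were highest. A lower share of tumour stays open, since the library was singled out by genes of these lists. A 4W library under a 36W label was not excluded. In the first WT library of 36W, 47.7% of the genes that differ between 36W and 4W in KO lay nearer the 4W mean. The other WT libraries of 36W had 20.6% or less and those of 4W had 80.7% to 87.0%. A share below every WT library of 4W argues against that label. The first bound, at most 1 in 3 of the genes and written before the test, was not met. A second bound, which was met, was set after the result was seen and cannot exclude the label.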

How the results depend on the processing

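The fits of 17 and 12 libraries are tests chosen only after the result was seen. KO against WT at 2D, 23 genes in the first analysis, gave 84 with no filter, 7 with limma-voom, 752 with DESeq2, 101 in the fit of all 18 libraries and 628 in the fit of 17. At 4W the 814 genes became 1297 with DESeq2, 439 in the fit of all 18 and 287 with at least a 2-fold change. At 36W the 5 genes became 47 with no filter, 296 with DESeq2, 401 in the fit of all 18 and 549 in the fit of 17. The difference 2D minus 4W gave 125 with library size only and 628 with DESeq2, against 199. The difference 36W minus 4W gave 568 with DESeq2, 134 in the fit of 17 and 9 in the fit of 12, against 84. The difference 36W minus 2D gave 237 with library size only and 1125 with DESeq2, against 453. The overlap of 12 genes became 51 in the fit of all 18 and 198 with DESeq2. Near Nfe2l2 at 36W, 0.588% of genes within 20 Mb were called, against 1.09% within 10 Mb. Of the 12, 20 and 22 lists called at 2D, 4W and 36W, fry called 0, 1 and 0 and an estimated correlation left 0, 0 and 0.

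Leaving out 1 library gave 1 to 1853 genes at 2D, 360 to 823 at 4W and 0 to 36 at 36W. The differences ranged from 82 to 531 (2D minus 4W), 9 to 351 (36W minus 4W) and 104 to 757 (36W minus 2D). WT gave 2232 to 3427 (36W against 4W) and 4389 to 5005 (2D against 4W), KO gave 3209 to 4175 and 2178 to 2953, and the list tests 10 to 15, 14 to 29 and 19 to 27. Signs turned for the general hepatocyte median at 2D with library size only (-0.0193 from 0.08), Epcam at 2D without WT replicate 3 (0.0540, range -2.69 to 0.0540) and Mup20 at 36W without WT replicate 1 (0.522, range -2.25 to 0.522). Epcam measured 53.8 CPM in WT replicate 3 of 2D against 4.13 and 4.40 CPM in the other WT libraries of 2D. Mup20 in WT replicate 1 of 36W lay far above all other libraries of 36W, as given above. Each of these 2 signs thus hung on 1 high library in the WT mean. Why those libraries were high was not tested, nor was the cause for the hepatocyte median.

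Libraries share replicate numbers, but not every library correlated best with its own number (same-number correlations -0.13 to 0.33), so they were not treated as pairs. With the replicate block the counts were 13 at 2D, 894 at 4W and 0 at 36W, 194, 142 and 546 for the differences 2D minus 4W, 36W minus 4W and 36W minus 2D, and 3124, 5466, 4479 and 3606 for the times.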

Other observations

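The tests of this part were planned, and only the genes shown were chosen after the result was seen. Immune cell genes also changed with time. In WT at 36W against 4W, 7 of 12 B and plasma cell genes were higher, with the antibody light chain Igkc up by 4.30 and the joining chain Igj by 4.62 (camera adjusted p = 0.000495; adjusted p = 0.337 with an estimated correlation), and in KO 2 of 12 were higher, Igkc by 2.67 and Igj by 2.94. At 2D the neutrophil genes were higher than at 4W in 7 of 11 in WT and 3 of 11 in KO (camera adjusted p = 0.000191 and 0.00486; adjusted p = 0.445 and 0.529 with an estimated correlation). Lactotransferrin, Ltf, stood at 72.6 ± 37.8 CPM in WT at 2D and had a count of 0 in the WT libraries of 4W.

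The imprinted genes H19 and Igf2 were high at 2D. H19, the non-coding neighbour of Igf2, measured 4071 ± 796 CPM in WT and 6584 ± 266 CPM in KO at 2D, and 24.3 ± 30.6 against 201 ± 81.6 CPM at 36W (adjusted p = 0.31). Igf2 had 2.18 ± 1.35 CPM in WT and 3.34 ± 2.27 CPM in KO at 36W. Csn3, a milk casein gene, had a count of 0 in the 4W libraries and 7.83 ± 6.62 CPM in WT and 42.8 ± 32.3 CPM in KO at 36W. Prom2, a membrane protein gene, stood at 22.2 ± 17.5 CPM in the WT libraries of 36W. No biological explanation was tested for these genes.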
